A study of Homo sapiens with 12 samples.

How the data were processed

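The authors deposited 1 table of raw read counts per gene, with a column for each of the 12 libraries, and every column was matched to a sample by its name. Per the labels, total RNA was extracted with Trizol, had integrity numbers above 9, and was made into libraries with a TruSeq stranded mRNA kit and sequenced as paired reads of 150 bases on a NextSeq500. Per the submitters' notes, reads were converted with bcl2fastq 2.17 and the genome build was GRCh38. The column names carry the ending that the aligner STAR writes. The counting tool, its strand setting and the gene annotation are not given in the sources used here. GENCODE 29 held 58542 of the 60617 gene identifiers of the table, 57296 with the same symbol, and its positions are used.

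All steps from the counts onward were run with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3 and with python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 16306. Library sizes were scaled with TMM factors. All 12 libraries were fitted in 1 edgeR quasi-likelihood model with a coefficient for each of the 4 groups. The E2 response in each line, the COP1 comparison in each treatment, the difference of the E2 responses and their mean were tested as contrasts, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Standard errors are the absolute log2 fold change divided by the square root of the F statistic.

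The model, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those named here as later choices. The rule named, in each comparison of 2 groups, the 12 largest log2 fold changes in each direction among called genes with a mean log2 CPM of at least 1 and no overlap between the groups. It further took up to 4 called members and up to 2 others from each list, and COP1, ESR1, PGR, GREB1, TFF1, CXCL12, MYC, CCND1, TP53, CDKN1A, JUN, ETV4, ETV5, GATA3 and FOXA1. For the difference of the responses, where no gene passed, it took the 5 smallest p-values. PMAIP1 and THBS1 among the calls of the paired fit in that difference, and the genes printed per library other than COP1, were picked after their values were seen.

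The 24 gene lists came from textbook knowledge: estrogen-induced, estrogen-repressed, luminal identity, basal and mesenchymal, stromal and leukocyte, estrogen receptor coregulators, COP1 complex, COP1 substrates, AP-1 targets, ETS and MAP kinase targets, p53 targets, G1/S and replication, mitosis, ribosome biogenesis, sterol synthesis, fatty acid synthesis, unfolded protein response, interferon response, NF-kappaB targets, hypoxia, circadian clock, immediate early, mitochondrially encoded, and ligands and growth factor genes. Each was tested with camera in limma (preset correlation 0.01, two-sided), adjusted over the 24 lists within a comparison, and again with a correlation estimated from the data and with fry. A list of aryl hydrocarbon receptor targets was written after CYP1A1 and CYP1B1 had been seen.

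The size of the E2 response was compared over the genes called in the mean response of both lines, which favours neither line. The replicate numbers were taken as pairing the libraries of 2 groups where the deviations of libraries with the same number correlated above 0.1 across genes for every number. That held for both E2 comparisons and for COP1 depletion in untreated cells, and not in E2-treated cells, where 1 of the 3 values was 0.098. This check was made before the calls of the paired and unpaired fits were compared. Of the 12 libraries, 6 correlated best with libraries of their own number. Replicate 1 correlated with replicate 2 of the other group at r of 0.121 to 0.437, and the difference between replicates 1 and 2 correlated between groups at r of −0.189 to 0.0679. The check thus did not show replicates 1 and 2 to be paired, and these values were computed after the fits were compared.

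Before use, the same steps were run on simulated changes in counts with this design. Of genes changed 2-fold, 46.3% were recovered in the comparison of the control groups with and without E2 and 53.8% in that of the untreated lines, and of genes changed 4-fold 85.5 and 91.1%.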

Results

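RNA sequencing measured gene expression in MCF7, an estrogen receptor-positive human breast cancer cell line, carrying either a control shRNA or an shRNA against COP1, the substrate-binding part of an E3 ubiquitin ligase. The cells had been kept without estrogen and were then left untreated or given 10 nM estradiol (E2), the ligand of estrogen receptor alpha, for 5 hours. The 12 libraries formed 4 groups of 3: control untreated, control with E2, COP1-depleted untreated and COP1-depleted with E2. Total counts, in units of 1e6, ran from 18.2 to 21.3 per library with a median of 19.8. Of 60617 genes in the table, 16306 had enough counts to be tested, and they held at least 99.8768% of the counts of every library. Levels are normalised counts per 1e6 counts (CPM) as mean ± SD, changes are log2 fold changes ± SE from the edgeR model, n = 3 in each group, and positions are on GRCh38 with GENCODE 29 genes. The labels call the replicates biological without saying whether they were separate cultures, so the p-values measure the spread between these samples.

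COP1 itself (ENSG00000143207, chromosome 1, 175944831 to 176207493, minus strand) was low in every library with its shRNA. In control cells its level was 57.2, 60.3 and 70.5 CPM in untreated replicates 1 to 3 and 57.7, 56.9 and 65.2 CPM with E2. In COP1-depleted cells it was 6.61, 7.48 and 9.38 CPM untreated and 7.82, 6.04 and 9.03 CPM with E2. These libraries kept 10.5, 11.9 and 15% of the mean control level without E2 and 13, 10.1 and 15.1% with E2. COP1 fell by 3.00 ± 0.17 in untreated cells (adjusted p = 9.5e-07) and by 2.97 ± 0.17 in E2-treated cells (adjusted p = 1.42e-06). E2 gave COP1 a log2 fold change of −0.06 in control cells (adjusted p = 0.972).

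The cell lines were split by the leading principal component, which held 76.3% of the variance of the 2000 most variable genes. The next component held 9.20% and set the third replicate of every group apart from the other two. CDKN1A, a cyclin-dependent kinase inhibitor, showed this in untreated COP1-depleted cells with 1645, 1677 and 985 CPM in replicates 1 to 3. The squared deviation between replicates 1 and 2 was 1.35 to 2.86 times that of counting noise (median over genes), against 7.92 to 10.4 times where the third replicate was one of the pair. Deviations of libraries with the same replicate number correlated between the untreated and E2-treated groups (lowest r across genes 0.104 in control cells and 0.373 in COP1-depleted cells) and between the lines without E2 (lowest r 0.120). Replicates 1 and 2 correlated across numbers about as well (r 0.193 and 0.437 in control cells, 0.371 and 0.428 in COP1-depleted cells), and their difference did not correlate between treatments (r −0.136 and 0.0291), so only the third replicate was shown to go with its number. Values from a fit with replicate number as a block, called paired here, are given where they differ.

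**Figure D1:**
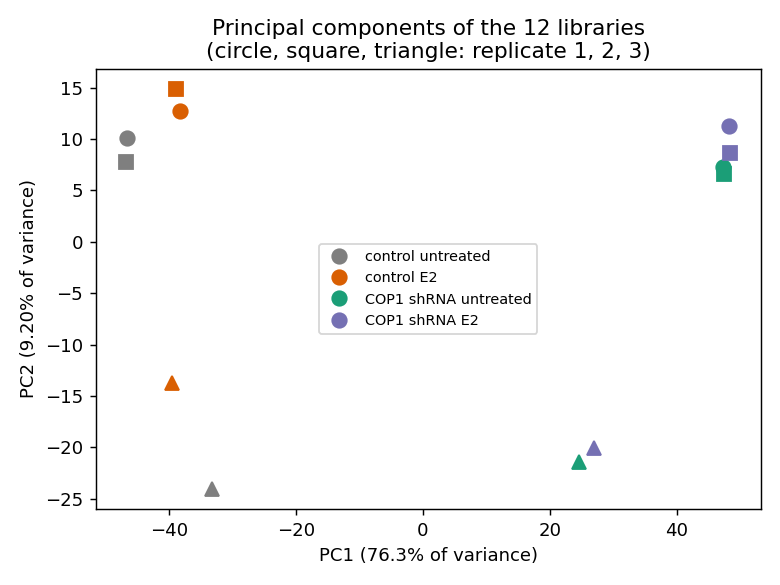
First principal components of the 12 libraries, with the share of variance on each axis; colours mark the groups and circles, squares and triangles mark replicates 1, 2 and 3. PC1 (76.3% of the variance) parts control from COP1-depleted cells and PC2 (9.20%) parts the third replicates from the others.

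E2 in control cells, the reference response of the line, raised known estrogen receptor targets within 5 hours. GREB1 (ENSG00000196208, chromosome 2, 11482341 to 11642788, plus strand), a cofactor and classical target of the receptor, rose from 67.4 ± 23.3 to 274 ± 122 CPM (log2 2.02 ± 0.34, adjusted p = 0.0168). The carbonic anhydrase gene CA12 rose from 19.9 to 96.4 CPM (2.28 ± 0.20, adjusted p = 0.000554), and the amino acid transporter gene SLC7A5 from 137 to 594 CPM (2.11 ± 0.20, adjusted p = 0.000593). TSKU (ENSG00000182704, chromosome 11, 76782251 to 76798154, plus strand), which encodes a secreted proteoglycan, rose by 3.40 ± 0.31, and EGR3, an early response transcription factor, by 3.34 ± 0.40. KCNJ8, a potassium channel subunit, fell from 27.1 to 9.60 CPM (−1.5 ± 0.20, adjusted p = 0.00433). TP53INP1, a p53-induced regulator of cell death and autophagy, fell from 383 ± 2.67 to 236 ± 34.5 CPM (−0.70 ± 0.11, adjusted p = 0.0109).

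Of the 32 genes on the list of estrogen-induced genes, 15 rose, none fell and 17 did not pass over all genes, and 27 passed adjusted over the list alone. The list shifted up by a median of 0.98 (camera adjusted p = 3.22e-41, and adjusted p = 0.000555 with an estimated correlation), and all 32 members had a positive fold change. Besides GREB1, CA12 and EGR3, these included HSPB8, a small heat shock protein (1.96 ± 0.18), the potassium channel gene KCNK5 (2.42 ± 0.31) and IGFBP4, which binds insulin-like growth factors (103 to 206 CPM, adjusted p = 0.00105). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434, plus strand), a transcription factor of cell growth, went from 20.7 ± 12.1 to 77.0 ± 38.3 CPM without passing (1.89 ± 0.49, adjusted p = 0.124), and passed in the paired fit (1.93, adjusted p = 1.71e-06). The progesterone receptor gene PGR had 2.21 ± 0.50 (adjusted p = 0.0657, paired 0.00667), the trefoil factor gene TFF1 0.83 ± 0.22 (0.128, paired 0.0387) and the cyclin gene CCND1 0.72 ± 0.27 (0.360, paired 0.00242). MYC and CCND1 also passed without control untreated replicate 3 (0.0477 and 0.0489), and PGR without control E2 replicate 3 (0.00403). The third libraries stood apart in these genes: GREB1 with E2 was at 332, 357 and 133 CPM in replicates 1 to 3, and MYC at 52.3, 57.6 and 121 CPM. ESR1, the gene of the receptor, had −0.02 (adjusted p = 0.994). GREB1 was not called without control untreated replicate 1 (0.0585) or 2 (0.0721) or control E2 replicate 1 (0.0848) or 2 (0.0931).

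Ribosome biogenesis genes moved up with them: 7 of 25 rose, none fell and 18 did not pass, and 20 passed adjusted over the list alone. Their median was 0.55 (camera adjusted p = 1.26e-21, adjusted p = 0.0248 with an estimated correlation, and 0.0595 with an estimated correlation in the paired fit). RRS1, needed for large ribosomal subunit assembly, rose by 1.06 ± 0.17 (adjusted p = 0.0117), and DKC1, which modifies ribosomal RNA, by 0.67 ± 0.12 (0.0204). RRS1 was not called without control untreated replicate 2 (0.0540) or control E2 replicate 2 (0.0787), nor DKC1 without replicate 1 or 2 of control untreated (0.0897 and 0.0863) or of control E2 (0.0969 and 0.111). Among 18 estrogen-repressed genes none rose, 1 fell (TP53INP1) and 17 did not pass, with 4 adjusted over the list alone. Their median was −0.60 (camera adjusted p = 1.88e-07, adjusted p = 0.133 with an estimated correlation), and 5 fell in the paired fit. TP53INP1 was not called without control untreated replicate 2 (0.0607), control E2 replicate 1 (0.0710) or 2 (0.0787).

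Over all genes, E2 raised 147 and lowered 12 in control cells, 159 in total, of which 52 rose and 3 fell at least 2-fold. The paired fit called 590 (409 higher, 181 lower), and replicates 1 and 2 alone gave 3456 (1947 higher, 1509 lower). The squared deviation between replicates 1 and 2 was only 1.35 to 2.86 times counting noise. Counts from these replicates alone, here and below, may thus be too high. The fit of all 12 libraries also takes replicates 1 and 2 as separate samples, and the labels do not say whether they were separate cultures. The count of 159 was 51 without control untreated replicate 1, 33 without replicate 2, 47 without control E2 replicate 1, 33 without replicate 2 and 331 without replicate 3.

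E2 in COP1-depleted cells raised 4 genes past the threshold and lowered none, a direction that some other settings did not keep (below). CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610, minus strand), a cytochrome P450 that oxidises foreign compounds and estrogens, rose from 145 ± 46.0 to 1155 ± 299 CPM (2.99 ± 0.31, adjusted p = 0.00730). In control cells it rose from 130 ± 55.0 to 681 ± 111 CPM (2.39 ± 0.30, adjusted p = 0.00386). The Rap GTPase regulator SIPA1L2 rose from 102 ± 8.25 to 213 ± 38.8 CPM (1.06 ± 0.12, adjusted p = 0.00730), the vitamin D receptor gene VDR by 1.03 ± 0.14 (0.0416) and EDC3, an mRNA decapping factor, by 0.78 ± 0.09 (0.00730). EDC3 (ENSG00000179151, chromosome 15, 74630558 to 74696292, minus strand) lies downstream of CYP1A1 on the same strand. All 3 libraries with E2 were above all 3 without it for each of the 4 genes (chance 5% for a gene not chosen by its call).

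Estrogen-induced genes in COP1-depleted cells had a median of 0.32, with none of 32 past the threshold, 4 adjusted over the list alone and 2 rising in the paired fit (camera adjusted p = 0.000221, but adjusted p = 0.312 with an estimated correlation). GREB1 went from 11.5 ± 0.767 to 27.9 ± 6.28 CPM (1.28 ± 0.36, adjusted p = 0.308, paired 0.0528). MYC went from 32.4 ± 13.2 to 49.3 ± 28.1 CPM (0.61 ± 0.48, adjusted p = 0.731, paired 0.0386), and IGFBP4 from 46.7 to 69.6 CPM (0.58 ± 0.11, adjusted p = 0.111, paired 0.0210). Ribosome biogenesis genes had a median of 0.38 with none of 25 past the threshold, 14 adjusted over the list alone and 5 rising in the paired fit (camera adjusted p = 2.08e-11, adjusted p = 0.276 with an estimated correlation). The unadjusted p was under 0.05 in 1623 genes in COP1-depleted cells and in 1518 in control cells. For the count of 4, the paired fit gave 69 (57 higher, 12 lower), DESeq2 133 (112 higher, 21 lower), no filter 252 (103 higher, 149 lower), and replicates 1 and 2 alone 2708 (1212 higher, 1496 lower). The count was 0 without COP1-depleted untreated replicate 1 or 2 (CYP1A1, SIPA1L2 and EDC3 each at 0.0640 and 0.121), 7 without control untreated replicate 3 and 40 without control E2 replicate 3, and VDR was lost without any 1 of 10 libraries (0.0528 to 0.288).

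Whether COP1 loss altered the E2 response was tested as the difference of the responses between the lines. Estrogen-induced genes responded less in COP1-depleted cells: the median difference was −0.75, and 31 of 32 members had a negative one. The list passed camera (adjusted p = 3.06e-24) and kept its call with an estimated correlation (adjusted p = 0.00378), although not in the paired fit (adjusted p = 0.0529 with an estimated correlation). No member passed over all genes, 14 passed adjusted over the list alone, and 4 were lower in the paired fit. CXCL12, a chemokine gene, had a difference of −2.07 ± 0.52 (adjusted p = 0.871, paired 0.0318) and MYC −1.29 ± 0.68 (0.995, paired 0.00322). CXCL12 was already higher in untreated COP1-depleted cells, as was MYC in the paired fit (below). Their differences thus do not tell a weaker induction from a higher start. GREB1 had −0.74 ± 0.49 and HSPB8 −1.45 ± 0.24 (adjusted p = 0.426), which passed without control untreated replicate 3 (0.00125).

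No gene passed for this difference in the unpaired edgeR fit with the filter on low counts, with 659 at an unadjusted p under 0.05. The paired fit called 16, all with a smaller response in COP1-depleted cells, among them MYC, CXCL12, the cell death gene PMAIP1 of the BCL2 family and the matrix protein gene THBS1. DESeq2 called 24, limma-voom 0, and replicates 1 and 2 alone 651. A single gene was called without control untreated replicate 3 or without control E2 replicate 3.

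E2-responsive genes were also compared as sets chosen from the mean response of both lines, which called 293 genes (250 higher, 43 lower; 983 in the paired fit). The 250 raised genes had a median of 0.66 in control and 0.50 in COP1-depleted cells, with a median difference of −0.131, and 181 of them (72.4%) responded less without COP1 (camera p = 5.03e-12, but p = 0.0806 with an estimated correlation). With 1 library left out, the raised genes were chosen again from that fit. The median difference was then −0.212 over 146 genes without control untreated replicate 1 and −0.215 over 138 without replicate 2. Without control E2 replicate 3 it was −0.203 over 474 genes. The median difference was smaller with the block, −0.0745 over 675 raised genes, of which 61.2% responded less (p = 0.250 with an estimated correlation). With the block by line it was −0.0718 over 937 raised genes. In the 40 raised at least 2-fold the medians were 1.90 and 1.05, the median difference was −0.807 and 36 responded less (camera p = 1.21e-20, p = 1.48e-05 with an estimated correlation). The 43 lowered genes had medians of −0.56 and −0.41 (median difference 0.0728, camera p = 0.00505, p = 0.218 with an estimated correlation). Lowered genes chosen again in the paired fit had a median difference of 0.118 over 308 genes. Those chosen without COP1-depleted E2 replicate 3 had −0.0391 over 58 genes. Without COP1-depleted untreated replicate 3 the value was −0.00875 over 37 genes. Of the genes raised by E2, 3 were called in both lines where chance gives 0.0361 (paired fit 48, chance 1.43). The count of 293 was 158, 149 and 612 without control untreated replicates 1 to 3, 153, 146 and 601 without control E2 replicates 1 to 3, 154 and 155 without COP1-depleted untreated replicates 1 and 2, and 165 without COP1-depleted E2 replicate 2. It was 176 without COP1-depleted E2 replicate 1 and 4792 (2426 higher, 2366 lower) from replicates 1 and 2 alone.

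**Figure D2:**
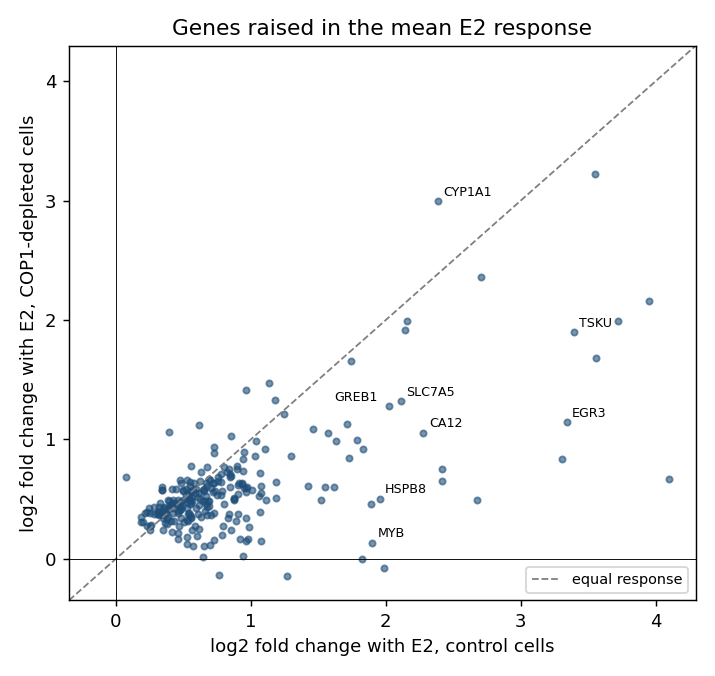
Log2 fold change with E2 in control cells (x axis) and in COP1-depleted cells (y axis) for the 250 genes raised in the mean E2 response, one point per gene, with the dashed line marking an equal response. Below the line lie 181 of the 250 genes.

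COP1 depletion in untreated cells, the comparison of the lines without hormone, went with differences in 35.8% of the tested genes. The estrogen receptor gene ESR1 (ENSG00000091831, chromosome 6, 151656691 to 152129619, plus strand) fell from 213 ± 36.0 to 76.3 ± 21.1 CPM (−1.48 ± 0.24, adjusted p = 0.000598), and GREB1 from 67.4 ± 23.3 to 11.5 ± 0.767 CPM (−2.55 ± 0.36). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand) rose from 110 ± 48.1 to 1436 ± 390 CPM (3.71 ± 0.36, adjusted p = 2.01e-05). CEMIP (ENSG00000103888, chromosome 15, 80779343 to 80951776, plus strand), a hyaluronan-binding protein, rose from 5.33 ± 1.79 to 475 ± 205 CPM (6.48 ± 0.44), and PTGES, a prostaglandin E synthase, by 6.15 ± 0.50. The calcium-dependent membrane-binding protein gene ANXA6 fell from 132 ± 22 to 9.43 ± 2.92 CPM (−3.81 ± 0.25).

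Targets of the p53 transcription factor rose together: 19 of 24 rose, none fell and 5 did not pass, with 19 adjusted over the list alone. Their median was 1.52 (camera adjusted p = 4.14e-10, but adjusted p = 0.377 with an estimated correlation). Besides CDKN1A these were, among others, the death receptor gene TNFRSF10B (1.89 ± 0.19), GDF15, a stress-induced cytokine (15 ± 4.36 to 371 ± 181 CPM), DDB2 of DNA repair (1.53 ± 0.12) and TP53INP1 (383 ± 2.67 to 1088 ± 33.7 CPM). The third COP1-depleted library lay nearer to the control cells for CDKN1A (985 CPM against 1645 and 1677) and GDF15 (163 against 490 and 462). TP53 itself had −0.16 (adjusted p = 0.131).

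Sterol synthesis genes also rose, 17 of 22, with none falling, 5 not past and 18 adjusted over the list alone (median 0.95, camera adjusted p = 2.79e-06, adjusted p = 0.613 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose from 142 ± 30.5 to 526 ± 179 CPM, and SREBF2, its transcriptional regulator, by 1.02 ± 0.12. HMGCS1 was at 633 and 626 CPM in COP1-depleted replicates 1 and 2 and at 320 CPM in the third. Among AP-1 targets 12 of 19 rose, 1 fell and 6 did not pass, with 14 adjusted over the list alone (camera adjusted p = 6.54e-05, adjusted p = 0.167 with an estimated correlation). PLAUR, the urokinase receptor, rose by 3.48 ± 0.47. Of 19 ETS and MAP kinase targets 9 rose, 1 fell and 9 did not pass, with 11 adjusted over the list alone (camera adjusted p = 0.000821, adjusted p = 0.167 with an estimated correlation). DUSP5, a MAP kinase phosphatase, rose by 2.95 ± 0.30 and the receptor kinase gene EPHA2 by 2.63 ± 0.31. For NF-kappaB targets the count was 8 of 12 higher, none lower and 4 not past, with 11 adjusted over the list alone (camera adjusted p = 0.00242, adjusted p = 0.395 with an estimated correlation), and TNFAIP3, an inhibitor of the pathway, rose by 1.73 ± 0.17.

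Genes of the COP1 complex list went both ways, with 5 of 19 higher, 3 lower, 11 not past and 8 adjusted over the list alone (camera adjusted p = 0.374). That list also holds the COPS genes of the COP9 signalosome. COP1, the target of the shRNA, is on it and was among the lower genes. TRIB1, a pseudokinase adaptor of COP1, rose from 50.9 ± 3.76 to 286 ± 1.24 CPM (2.49 ± 0.09), and DDB1, an adaptor of cullin ligases, fell from 785 ± 46.6 to 376 ± 14.5 CPM (−1.06 ± 0.09). The mRNAs of proteins that COP1 is known to target counted 3 of 13 higher, 1 lower and 9 not past, with 4 adjusted over the list alone (camera adjusted p = 0.354). ETS2 rose by 0.93 ± 0.13, and JUN by 0.75 ± 0.22 (adjusted p = 0.02), a call lost without control untreated replicate 3 (0.0647) and COP1-depleted untreated replicates 1 (0.0854) and 2 (0.0759). Estrogen-induced genes were split, with 5 of 32 higher, 8 lower, 19 not past and 13 adjusted over the list alone (camera adjusted p = 0.601). CXCL12 rose by 2.29 ± 0.39, IGFBP4 fell by 1.14 ± 0.11, and MYC had 0.65 ± 0.48 (adjusted p = 0.324, paired 0.000141). In luminal identity genes 7 of 20 were higher, 3 lower and 10 not past, with 12 adjusted over the list alone (camera adjusted p = 0.276). The tight junction gene CLDN4 rose by 1.84 ± 0.14.

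Over all genes, 5839 were called in untreated cells (35.8% of those tested), 2879 higher and 2960 lower, of which 1112 and 1247 at least 2-fold. The paired fit called 7966, replicates 1 and 2 alone 9852, and with 1 library left out the count was 4062 to 6304. With the block, the lists of mitosis genes (15 of 21 lower, camera adjusted p = 0.000519, unpaired 0.0600 with 3 lower), hypoxia genes (0.0233, unpaired 0.0600) and mitochondrially encoded genes (0.0417, unpaired 0.0984) also passed, none of them with an estimated correlation (adjusted p = 0.560, 0.560 and 0.712). Leaving out COP1-depleted untreated replicate 1 or 2 took the lists past the threshold from 5 to 8. Mitosis and hypoxia genes also passed without control untreated replicate 3 (0.000272 and 0.0217, the mitosis median going from −0.447 to −0.760) or control E2 replicate 3 (0.0317 and 0.0487). Without control untreated replicate 2 the mitosis median shrank to −0.258.

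COP1 depletion in E2-treated cells, the comparison under hormone, showed lower levels of the receptor gene and of many of its targets. ESR1 fell from 210 ± 38.2 to 77.3 ± 24.7 CPM (−1.44 ± 0.24, adjusted p = 0.000778), and GREB1 from 274 ± 122 to 27.9 ± 6.28 CPM (−3.29 ± 0.36). Of 32 estrogen-induced genes 21 fell, 2 rose and 9 did not pass, with 25 adjusted over the list alone (median −0.91, camera adjusted p = 5.48e-07, adjusted p = 0.199 with an estimated correlation). PGR (−3.32 ± 0.54), KCNK5 (−2.93 ± 0.33) and IGFBP4 (−1.57 ± 0.11) fell, whereas MYC had −0.64 ± 0.47 (adjusted p = 0.321) and TFF1 −0.59 (adjusted p = 0.0509). TFF1 passed without control untreated replicate 1 (0.0494) or 3 (0.0147) or control E2 replicate 3 (0.0285). Ribosome biogenesis genes had 9 of 25 lower, none higher and 16 not past, with 10 adjusted over the list alone (median −0.30, camera adjusted p = 0.00188, adjusted p = 0.507 with an estimated correlation). Their median was −0.461 without control E2 replicate 3.

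p53 targets were higher with E2 as without it: 18 of 24 rose, none fell and 6 did not pass, with 19 adjusted over the list alone (camera adjusted p = 1.10e-10, adjusted p = 0.255 with an estimated correlation). CDKN1A rose from 111 ± 27.8 to 1484 ± 466 CPM and TP53INP1 from 236 ± 34.5 to 894 ± 40.7 CPM. For AP-1 targets 11 of 19 rose, 1 fell and 7 did not pass, with 14 adjusted over the list alone (camera adjusted p = 0.000960, adjusted p = 0.255 with an estimated correlation). Of ETS and MAP kinase targets 8 of 19 rose, 1 fell and 10 did not pass, with 10 adjusted over the list alone (0.00935, adjusted p = 0.255 with an estimated correlation). Sterol synthesis genes had 11 of 22 higher, none lower and 11 not past, with 16 adjusted over the list alone (0.000485, adjusted p = 0.716 with an estimated correlation). NF-kappaB targets had 5 of 12 higher, none lower and 7 not past, with 5 adjusted over the list alone (0.0151, adjusted p = 0.507 with an estimated correlation). CEMIP rose by 6.06 ± 0.43, TRIB1 by 2.18 ± 0.09, and the trefoil factor gene TFF3 fell by 3.75 ± 0.63.

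With E2, 5634 genes were called (2852 higher, 2782 lower), with 3885 to 6184 when 1 library was left out and 9463 from replicates 1 and 2 alone. Of the genes called in both treatments, 2165 were higher in both and 2143 lower in both, where chance gives 504 and 505, and 3 went opposite ways. Some called genes share exonic length with a gene on the other strand (PLAU, ICAM1, IRF1, DDIT3) or the same strand (CTSD), and the strand setting of the counting was not given, so reads of the neighbour were not told apart.

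**Figure D3:**
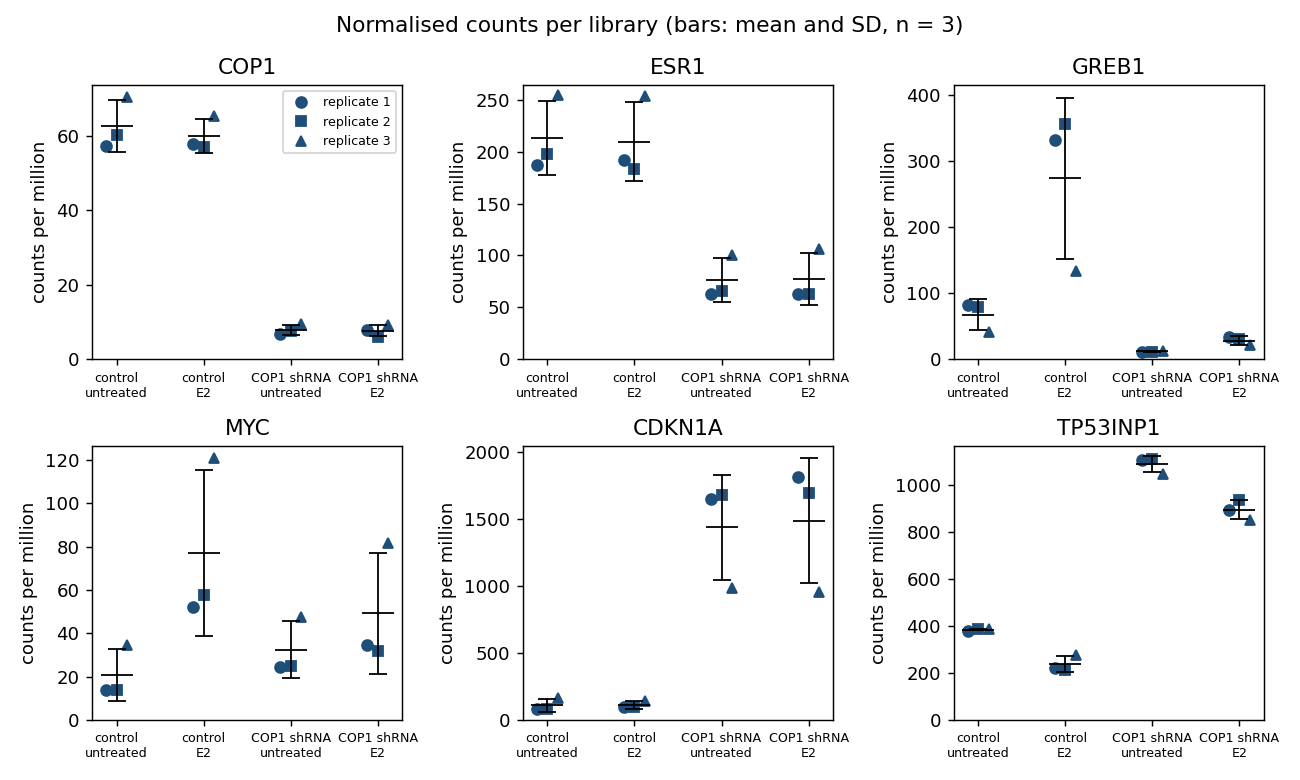
Normalised CPM of COP1, ESR1, GREB1, MYC, CDKN1A and TP53INP1 in each of the 12 libraries (markers show replicates 1, 2 and 3), with the mean and SD of each group as bars (n = 3). COP1 is between 6.04 and 9.38 CPM in the COP1-depleted libraries and between 56.9 and 70.5 CPM in the control ones.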

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

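The test of the third libraries below, and the values from replicates 1 and 2 alone, were chosen only after the result was seen. The differences listed were picked out because the E2 response differed between control and COP1-depleted cells in a test of the difference itself.

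Genes raised by E2 responded less in COP1-depleted cells: the median difference was −0.131 over the 250 raised genes and −0.807 over the 40 raised at least 2-fold. Of the 40, 36 had a smaller response. With the block the median difference was −0.0745 over 675 raised genes. With the genes chosen again, it was −0.212 over 146 and −0.215 over 138 genes without control untreated replicates 1 and 2. Without control E2 replicate 3 it was −0.203 over 474 genes. The third libraries are argued against as the cause, since without them the median over these 40 genes was −0.779 (quartiles −1.58 to −0.314). Different starting levels were not settled as the cause. The 162 raised genes whose untreated levels differed by under 0.5 between the lines had a median of −0.0921 (95% bootstrap interval over genes −0.165 to −0.0652). That interval takes genes as independent, whereas the 250 had an estimated correlation of 0.164, so it is too narrow. Among the 40, 13 such genes had a median of −1.22, so these matched genes still responded less. The lower ESR1 level in COP1-depleted cells, an effect of the shRNA on other genes, and the loss of COP1 itself stay open and were not tested. A weaker response through the receptor may be a candidate explanation, but the 250 genes did not pass with an estimated correlation (p = 0.0806).

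The 43 genes lowered by E2 had a median difference of 0.0728, toward a smaller fall in COP1-depleted cells, with p = 0.218 with an estimated correlation. The 2366 lowered genes chosen from replicates 1 and 2 alone had −0.0159. Estrogen-induced genes as a list had a median difference of −0.75, which held with an estimated correlation (adjusted p = 0.00378) but not with an estimated correlation in the paired fit (0.0529). Estrogen-repressed genes had 0.26 (camera adjusted p = 0.0318, adjusted p = 0.687 with an estimated correlation), lost without any 1 of 7 libraries (0.0527 to 0.220), with medians from −0.00269 without COP1-depleted E2 replicate 3 to 0.506 without COP1-depleted untreated replicate 3. Luminal identity genes had −0.17 (0.00533, adjusted p = 0.523 with an estimated correlation), lost without control untreated replicate 1 (0.0565) or control E2 replicate 3 (0.194), with medians from −0.261 to −0.0907. ETS and MAP kinase targets had −0.38 (0.0299, adjusted p = 0.381 with an estimated correlation), lost without any 1 of 6 libraries (0.0553 to 0.194), with a median of −0.0355 without control untreated replicate 1 and −0.569 at the other end, without control E2 replicate 2. Mitosis genes had 0.28 (0.0493, adjusted p = 0.802 with an estimated correlation) and turned to 0.0720 in median with the opposite test direction without control E2 replicate 3 (0.871), and were lost without any 1 of 5 other libraries (0.170 to 0.633). Ribosome biogenesis genes had −0.0526 (0.0299, adjusted p = 0.687 with an estimated correlation), lost without any 1 of 6 libraries (0.0522 to 0.229), with medians from −0.258 without control E2 replicate 3 to 0.00460 without control E2 replicate 1. Sterol synthesis genes had −0.21 (0.00533, adjusted p = 0.761 with an estimated correlation), lost without control untreated replicate 1 (0.0621), COP1-depleted untreated replicate 1 (0.111) or 2 (0.0553) or COP1-depleted E2 replicate 3 (0.382), with medians from −0.378 to −0.0484. Immediate early genes had −0.32 (0.00350, adjusted p = 0.0887 with an estimated correlation).

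Other splits of the libraries were counted for the mean E2 response and for the difference of the responses. For the mean response, 1 of 100 splits, the real one with 293 calls, gave as many calls and the highest other gave 2. That share is under 0.05, but the other splits mix treated and untreated libraries, which widens their spread. Replicates 1 and 2 were also nearly alike, so chance is made unlikely for that count and is not excluded. For the difference, with 0 calls, all 100 splits gave as many, which no split could fail to do, and the highest other gave 2, so that count decides nothing.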

How the results depend on the processing

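The counts for E2 rest on a spread that the third replicates set, and they varied most between settings. The values from replicates 1 and 2 alone were chosen after seeing the data, as was the block by line for the response size. Replicates 1 and 2 were nearly alike, so counts from them alone rest on a narrow spread and may be too high. The 540 named gene results pool the E2 and COP1 comparisons, and many were picked by their call. Of these, 261 were called and none of them reversed. The call was kept by 207 in every alternative that was run for them and gave a value. Not every alternative was: the block by line was fitted for the E2 comparisons and the difference only, only 6 libraries not for the difference, and DESeq2, the stricter filter and replicates 1 and 2 only left some results without a value. In the simulation, where few genes were changed, genes changed 1.5-fold were recovered in 10.1 to 16.9% of cases. Small changes were thus mostly missed where few genes change. Between the untreated lines 5839 genes were called, of which 1112 rose and 1247 fell at least 2-fold, so many smaller changes were detected there. The simulation also left out the shift shared by the third replicates. The cause of the changes below was not tested, except that comparing only 6 libraries, or leaving out 1, leaves fewer samples.

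Without the filter on low counts the calls were 451 for E2 in control cells, 252 for E2 in COP1-depleted cells, 66 for the difference and 736 for the mean E2 response. DESeq2 gave 373, 133, 24 and 673. The block gave 590, 69, 16 and 983, and the block by line 953, 230, 42 and 1580. Only the 6 libraries compared gave 38 and 0 for E2 in control and in COP1-depleted cells. Replicates 1 and 2 only gave 3456, 2708, 651 and 4792, with 9852 and 9463 for COP1 depletion in untreated and E2-treated cells. The block gave 7715 for the latter, where the hypoxia list then passed (0.0368 against 0.0702; 0.717 with an estimated correlation).

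Genes raised by E2 in both lines were 48 with the block, 78 with DESeq2 and 723 from replicates 1 and 2 only, and genes lowered in both 8, 6 and 465. For COP1 depletion in both treatments, replicates 1 and 2 only gave 3722 higher and 3972 lower. For the response size, the raised genes (−0.131) did not pass with an estimated correlation (p = 0.0806) or fry (0.0720), nor did the lowered genes (0.0728, p = 0.218 and 0.211). The sign was reversed, at −0.0159, over the 2366 lowered genes chosen from replicates 1 and 2 only.

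Lists past the threshold with an estimated correlation, and with fry, were 3 and 6 for E2 in control cells, 0 and 1 for E2 in COP1-depleted cells, 0 and 16 for COP1 depletion in untreated cells (8 with the block), 0 and 14 in E2-treated cells, and 1 and 1 for the difference (13 from replicates 1 and 2 only).

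Leaving out 1 library gave 33 to 331 calls for E2 in control cells, 0 to 40 in COP1-depleted cells, 4062 to 6304 and 3885 to 6184 for COP1 depletion in untreated and E2-treated cells, 0 to 1 for the difference and 146 to 612 for the mean E2 response. The response size, over the genes called in each fit, ran from −0.215 to −0.102 for raised and from −0.0391 to 0.243 for lowered genes. It was −0.0391 without COP1-depleted E2 replicate 3 and −0.00875 without COP1-depleted untreated replicate 3. List counts ran from 5 to 13, 3 to 6, 5 to 8 and 7 to 9 in the order above, and 2 to 12 for the difference. That count was 2 without control untreated replicate 1 and 5 without control untreated replicate 2 or control E2 replicate 3, where the test of the mitosis list reversed (median 0.0720, up to 0.564 without another library).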

Other observations

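The tests of depth, of a shared batch and of the third control libraries below were chosen only after the third replicates had been seen to stand apart, that of a single shift after the counts between the lines had been seen, and the list of aryl hydrocarbon receptor targets after CYP1A1 and CYP1B1 had been seen.

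The lists given next did not pass camera between the lines, where 35.8% of all tested genes were called without E2, so their counts do not mark them out. Without E2, 10 of 20 hypoxia genes were higher, none lower and 10 not past, with 11 adjusted over the list alone (camera adjusted p = 0.0600). EGLN3, an oxygen-sensing hydroxylase, rose by 1.64 and ANGPTL4, a lipase inhibitor, by 3.28. Unfolded protein response genes counted 7 of 20 higher, 2 lower and 11 not past (0.182). Fatty acid synthesis genes counted 7 of 16 higher, 3 lower and 6 not past (0.287), with ACLY, which makes acetyl-CoA, falling by 0.96. In the interferon response 7 of 17 fell, none rose and 10 did not pass (0.182), among them IFI6 (−1.60) and IFIH1 (−1.19). Clock genes went both ways, 4 of 17 higher, 4 lower and 9 not past (0.643), and PER3 fell by 1.66. Of ribosome biogenesis genes 7 of 25 fell, none rose and 18 did not pass (0.152). Mitochondrially encoded genes counted 4 of 13 lower and 9 not past. Immediate early genes counted 5 of 15 higher, 3 lower and 7 not past (0.152), estrogen-repressed genes 3 of 18 higher, 3 lower and 12 not past (0.835), and ligand and growth factor genes 2 of 17 higher, 4 lower and 11 not past (0.861). G1/S genes counted 4 of 26 higher, 4 lower and 18 not past (0.692), and receptor coregulators 3 of 20 higher, 2 lower and 15 not past (0.329). Of markers of other cell types, 2 of 11 measured basal and mesenchymal genes were higher, 3 lower and 6 not past (0.694), and 2 of 4 measured stromal and leukocyte genes were higher, 1 lower and 1 not past (0.861).

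With E2, the same comparison gave 8 of 20 hypoxia genes higher and 2 lower (camera adjusted p = 0.0702). On the COP1 complex list 9 of 19 were higher and 3 lower, COP1 itself among the lower (0.117). Unfolded protein response genes counted 6 of 20 higher and 3 lower (0.257) and COP1 substrates 3 of 13 higher and 2 lower (0.462). Of luminal identity genes 6 of 20 were higher and 7 lower (0.906), of estrogen-repressed genes 2 of 18 higher and 3 lower (0.646), of immediate early genes 4 of 15 higher and 5 lower (0.753) and of ligand genes 2 of 17 higher and 4 lower (0.710). Clock genes counted 3 of 17 higher and 5 lower (0.456), interferon genes 2 of 17 higher and 4 lower (0.456), fatty acid genes 4 of 16 higher and 3 lower (0.591), G1/S genes 4 of 26 higher and 2 lower (0.646) and mitosis genes 3 of 21 lower (0.456). Coregulators counted 2 of 20 higher and 1 lower (0.597), basal genes 1 of 11 higher and 3 lower (0.597), stromal genes 1 of 4 higher and 1 lower (0.591), and no mitochondrially encoded gene of 13 passed (0.456). Mitosis and hypoxia genes passed without control E2 replicate 3 (0.0194 and 0.0274), where the mitosis median went from −0.215 to −0.516. Without control E2 replicate 2 the mitosis median turned to 0.00427.

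Other lists passed camera for E2 in control cells and lost the call with an estimated correlation, except ETS and MAP kinase targets. That list had a median of 0.49 with none of 19 called, 4 adjusted over the list alone and 5 higher in the paired fit (camera adjusted p = 8.97e-06, adjusted p = 0.0315 with an estimated correlation, paired 0.172). Its median ran from 0.306 to 0.672 when 1 library was left out. Sterol synthesis genes had 0.32 (0.000445, adjusted p = 0.605 with an estimated correlation), immediate early genes 0.15 (0.00329, 0.0664), NF-kappaB targets 0.24 (0.0101, 0.331) and AP-1 targets 0.12 (0.0153, 0.314). Mitosis genes had −0.33 (0.00391, 0.644), interferon genes −0.33 (0.0109, 0.449), COP1 substrates 0.16 (0.0414, 0.154) and ligand genes 0.12 (0.0414, 0.644, and 0.0619 with camera in the paired fit). Without control E2 replicate 3, 5 lists passed instead of 12, and those lost were AP-1 (0.169), mitosis (0.886), interferon (0.237), ligands (0.623), COP1 substrates (0.113), NF-kappaB (0.169) and immediate early (0.0593). With 1 library left out the medians ran from 0.125 to 0.411 for AP-1, −0.562 to −0.0626 for mitosis, −0.546 to −0.0322 for interferon, 0.219 to 0.517 for NF-kappaB, 0.150 to 0.346 for immediate early and −0.000120 to 0.267 for ligand genes. Without control untreated replicate 1 the lost lists were AP-1 (0.0998), mitosis (0.143), interferon (0.373) and ligands (0.168), without replicate 2 mitosis (0.211) and ligands (0.119), and COP1 substrates were lost without control untreated replicate 3 (0.162) or control E2 replicate 1 (0.0502) or 2 (0.0677). The others did not pass: mitochondrially encoded 0.0726 (paired 0.0452), unfolded protein response 0.0822, p53 targets 0.0997, fatty acid synthesis 0.156, stromal and leukocyte 0.259, G1/S 0.297, COP1 complex 0.297, luminal identity 0.315, hypoxia 0.419, coregulators 0.594, clock 0.736 and basal 0.939. Some of these passed with 1 library left out: fatty acid synthesis (0.00186, median 0.255 against 0.0905) and the unfolded protein response (0.0135) without control untreated replicate 3, the latter also without control E2 replicate 2 (0.0204), G1/S (0.0196) without control untreated replicate 2, and mitochondrially encoded genes without any 1 of 3 libraries (lowest 0.0339). The fatty acid median shrank to 0.0376 without control untreated replicate 2.

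In COP1-depleted cells with E2, estrogen-repressed genes had a median of −0.26 (camera adjusted p = 0.0199, adjusted p = 0.655 with an estimated correlation) and luminal identity genes −0.13 (0.0473, adjusted p = 0.655 with an estimated correlation, paired 0.0624). The estrogen-repressed list was lost without COP1-depleted untreated replicate 3 (0.355, the median turning to 0.0176) or COP1-depleted E2 replicate 1 (0.176) or 2 (0.0848), and the luminal list without any 1 of 7 libraries (0.0550 to 0.189; medians −0.212 to −0.0781). The other lists there had adjusted p from 0.0631 for p53 targets and 0.151 for ETS and MAP kinase targets upward, with no member called. The p53 targets passed, toward lower levels, without COP1-depleted untreated replicate 3 (0.00102, median −0.168 against −0.0951), COP1-depleted E2 replicate 1 (0.00622) or 2 (0.00326) or control E2 replicate 3 (0.0439). Their median turned to 0.00394 without COP1-depleted E2 replicate 3. Sterol synthesis genes passed in opposite directions without COP1-depleted untreated replicate 3 (median −0.119, 0.0413) and COP1-depleted E2 replicate 3 (0.242, 0.0345), and G1/S genes passed without the latter (0.0345). In the difference of the responses the lists that did not pass had 0.0528 for NF-kappaB targets, 0.0676 for AP-1 targets (paired 0.0289), 0.0741 for stromal, 0.0875 for mitochondrially encoded, 0.194 for COP1 complex, fatty acid and ligand genes, 0.262 for interferon, 0.621 for coregulators, 0.647 for hypoxia, 0.830 for COP1 substrates, 0.854 for basal, p53, unfolded protein response and clock genes and 0.954 for G1/S genes. Of these, NF-kappaB targets passed without any 1 of 7 libraries (0.00265 to 0.0469) and mitochondrially encoded genes without any 1 of 3 (0.0131 to 0.0379). Without control untreated replicate 3, NF-kappaB (0.00265, median −0.593 against −0.282), AP-1 (0.0123), fatty acid (0.00147, median −0.265 against −0.0544), ligand (0.00540) and interferon genes (0.0191) passed. The NF-kappaB median shrank to −0.131 without COP1-depleted untreated replicate 1. The fatty acid median turned to 0.0235 without COP1-depleted E2 replicate 3. AP-1 targets also passed without control E2 replicate 2 (0.0264) or COP1-depleted untreated replicate 3 (0.0212), fatty acid and stromal genes without the latter (0.0459 each), and ligand genes without COP1-depleted E2 replicate 3 (0.00440).

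The third replicate stood apart in every group, and lower depth is argued against as the cause, since the third libraries had 1.00 times the mean total count of the others. A batch shared by the third libraries may be a candidate explanation, since their deviations correlated between the lines with r of at least 0.307 across genes, although genes are not independent replicates. Control cells mixed into the third COP1-depleted libraries are argued against as the whole cause, since the third control libraries stood apart as well (second component −13.7 and −24.1 against 7.73 to 14.9). A share of such cells was not settled: COP1 was at 15 and 15.1% of the control level in these libraries (10.1 to 13% in replicates 1 and 2) while they lay 25% of the way to the control cells on the first component, and 6 genes at under 5% of the control level in replicates 1 and 2 reached a median of 14.9% in replicate 3 (range 9.86 to 19.2%), between the bounds set beforehand, and the 2% limit first set left 1 gene. No biological explanation was tested, as the labels give none for the replicate number.

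More than 1 tested gene in 3 differed between the lines. A wrong scaling factor is argued against as the cause, since the single shift of all fold changes that left the fewest genes past the threshold left 99.7% as many, while normalization by the RLE method (99% of the calls kept) moved almost nothing and decides little. Copy number of large chromosome segments is argued against as the main cause. Untreated fold changes of genes 25 to 50 places apart correlated at r = 0.00587. That was above the highest of 200 shuffles (0.00420), so a small share was not excluded. The E2 comparison in COP1-depleted cells gave r = 0.0414, so the measure is not particular to copy number. The loss of COP1, an effect of the shRNA on other genes and a difference between the lines that came before depletion stay open, since the labels name no other shRNA, and they were not tested. For the comparisons of 2 groups, 3 libraries against 3 make 10 splits, too few for a share under 0.05: 1 of 10 gave as many calls in each, with the real counts 159, 4, 5839 and 5634 and the highest other 0.

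A hypothesis for CYP1A1 is that E2 treatment acted on the aryl hydrocarbon receptor, whose targets include CYP1A1 and CYP1B1. Of 7 other known targets (CYP1A2, AHRR, TIPARP, NQO1, ALDH1A3, ALDH3A1 and UGT1A6), the lower of the medians in the 2 lines was 0.524, in control cells, and camera passed in both lines (adjusted p = 0.00337 and 0.00362), which is consistent with the hypothesis. With an estimated correlation neither line passed (adjusted p = 0.102 and 0.102), and of the 7 only CYP1A2, near the lowest level tested, was called in control cells (1.72 ± 0.31, adjusted p = 0.0205), joined in the paired fit by TIPARP (1.33, adjusted p = 0.0294, unpaired 0.223). Of the 7, 5 had a positive fold change in control cells and 6 in COP1-depleted cells. NQO1 (−0.0861) and UGT1A6 (−0.212) were negative in control cells, and ALDH3A1 (−0.273) in COP1-depleted cells. AHRR has 2 entries in the table, and the entry found in GENCODE 29 replaced the other after a first result was seen. CYP1B1 rose by 2.15 ± 0.44 in control cells (adjusted p = 0.0423) and was lost without any 1 of 8 libraries (0.0567 to 0.202).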
